A study of Homo sapiens with 2 samples.

How the data were processed

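Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map histone H4 acetylated at lysine 5 (H4K5ac) in FaDu cells, an established human head and neck cancer cell line. There were 2 libraries: 1 from cells kept in normoxia and 1 from cells kept in 1% oxygen for 18 h. The sample labels give H4K5ac as the target, whereas the series design text names a different histone mark, and the target is given here as in the sample labels. The culture protocol also mentions knockdown of METTL4, but no label assigns a knockdown to either library. Libraries were sequenced as 75 bp single-end reads, per the labels' protocols.

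The authors deposited 1 peak list per library, so peaks were called separately in each sample. The build was hg38 and the tools were MACS2 and SICER, per the submitters' processing notes; the versions, the settings and any control library are not given in the sources used here. Each deposited peak has a position, an integer score, a fold enrichment at its summit, a −log10 p-value, a −log10 q-value and a summit offset. The deposited score equals 10 times the −log10 p-value rounded down in 100.0% of normoxia peaks and 99.998% of hypoxia peaks, so it follows p and not q. The deposited lists include 144 normoxia and 29 hypoxia peaks with a q-value above 0.05. The fold and q-value of a peak are the authors' values. They were used to rank, filter or describe peaks within their own list, and a difference in their values between libraries was not read as a change. Numbers of peaks past a q-value or fold threshold were compared between the lists, also by region. Pileups and backgrounds derived from the fold and p-value were used to compare depth and coverage between the libraries.

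The fold and p-value of each peak were solved together for its pileup (reads covering the summit) and local background, on the assumption that the fold is (pileup + 1) / (background + 1) and p is a Poisson tail. The pileup came out whole, within 0.02, for 100.0% of peaks in both lists. The lowest background, taken as the genome-wide one, was 3.13 reads in normoxia and 3.24 in hypoxia. The narrowest peaks were 245 bp and 215 bp wide. If these widths are the fragment lengths used in peak calling, the hypoxia library held 1.18 times as many reads as the normoxia library; with equal fragment lengths the ratio would be 1.04. Read totals are otherwise not stated, and intervals below cover counting error only.

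Peaks were compared by overlap of at least 1 bp. Chance overlap was taken from 100 circular shifts of the normoxia regions within chromosomes, in place of the shuffles first planned, for both directions of overlap. Gene spans were those of 19974 protein-coding genes on chromosomes 1 to 22 and X in the RefSeq table of GRCh38.p14, the assembly that hg38 names. The design called for promoters, but the table used gives neither strand nor transcript start sites. A gene was therefore counted as marked when a peak overlapped the 1000 bp either side of either end of its span. Such a peak can lie at the start or the end of transcription, can belong to a neighbour, and misses internal promoters. Exons, introns and UTRs were not distinguished. The planned search for hypoxia response elements needs genome sequence and was not analysed here. Strong peaks are those with a −log10 q-value of at least 10.

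With 1 library per condition, no test of the condition was possible and no p-values are given. Shares carry 95% exact binomial (Clopper-Pearson) intervals over regions, which are not replicates, and ratios of peak numbers carry intervals from the same method. Shares of regions weighted to a matching −log10 q-value distribution are the exception, and carry symmetric intervals that are not exact. For each of 9 gene lists fixed before the data were examined, members without a normoxia peak at a gene end were taken. The share of them with a hypoxia gene-end peak was placed among 10000 random lists of the same size. Those random lists were drawn from all genes without a normoxia gene-end peak. The ratio of peaks within 50000 bp of list genes was placed among 10000 random lists matched on normoxia peak number; this comparison, and the definition of strong peaks against the other list as deposited, were added after the data were seen. These percentiles describe the 2 libraries, and random lists that tied with a list counted in part towards its percentile. All list members (210 entries) matched the RefSeq table by symbol.

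The genes named were set by rule before the data were examined: 16 genes of hypoxia signalling and epithelial-mesenchymal transition (EMT) whatever their values; up to 10 genes marked in 1 library with no peak of the other within 2000 bp, ranked by fold, per direction; up to 4 members of each list; and the 5 genes with the highest fold per library. Of the genes this rule takes, all but 1 are named, and that 1 is not reported here. Other named genes are said to have been chosen after their values were seen. Alternatives were stricter q-values, equal list lengths, 50% reciprocal overlap, stitching within 1000 bp, and gene-end windows of 500 and 2000 bp; those added later are named with their values.

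Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9; overlaps were checked against bedtools 2.31.1 and gave equal counts. On simulated peaks the pileup was recovered exactly in 100.0% of 19932 peaks. For 2 simulated libraries that differed in depth only, the ratio of strong regions was 1.14 before thinning the deeper library and 1.01 after it. Of 200 simulated lists with a planted excess, 200 reached percentile 95, and of 200 unchanged lists 9 did. Most real lists had fewer members to place than the simulated ones. Members without a normoxia peak at a gene end numbered 4 for hypoxia-response, 6 for mesenchymal and EMT, 5 for squamous and 1 for histone acetylation genes. The simulation therefore does not show how readily an excess in such short lists would be found.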

Results

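The data were 2 peak lists of H4K5ac, an acetylation mark of active chromatin, from FaDu cells in normoxia and in hypoxia (1% oxygen, 18 h). The comparison asked how hypoxia alters the genomic distribution of this mark in a study of EMT, the loss of epithelial and gain of mesenchymal traits. Each condition had 1 library, so the difference between conditions has no replicate check. The normoxia list held 120033 peaks covering 59.2 Mb, and the hypoxia list held 258195 peaks covering 99.9 Mb. The hypoxia list thus had 2.15 times as many peaks over 1.69 times the length. Its peaks were narrower, with a median width of 294 bp against 356 bp. The smallest width also differed, at 215 bp in hypoxia and 245 bp in normoxia, and may reflect a peak-calling setting. Part of the difference in width may therefore not be a property of the mark. Peaks that overlapped the other list had a median width of 445 bp in each list, and hypoxia-only and normoxia-only peaks had 263 and 276 bp. The genome-wide background pileup was similar, at 3.24 reads in hypoxia and 3.13 in normoxia. It depends on fragment length as well as on reads, so it does not show equal depth. The implied hypoxia to normoxia ratio of reads was 1.18 with the inferred fragment lengths and 1.04 with equal ones.

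Strong H4K5ac peaks were mostly found in both conditions, and overlap was lowest among weak peaks. Of strong normoxia peaks 98.3% overlapped a hypoxia peak, and of strong hypoxia peaks 86.6% overlapped a normoxia peak. Of the normoxia peaks, 68.7% (82484; 95% interval 68.46 to 68.98%) overlapped a hypoxia peak, against a mean of 7.49% after shifting. Of the hypoxia peaks, 32.7% (84434; 32.5 to 32.9%) overlapped a normoxia peak, against 3.54% after shifting. In the strongest decile of each list the overlapped share was 99.99% for normoxia and 98.9% for hypoxia. In the weakest decile it was 43.0% and 10.9%. Among strong peaks, 6526 in hypoxia lacked any normoxia peak, and 497 in normoxia lacked any hypoxia peak. The normoxia peaks were compared with the longer list, so the counts and shares of the 2 libraries are not on equal terms. The share overlapped moved with the threshold: with a −log10 q-value of at least 10 in both lists it was 89.2% for normoxia and 56.7% for hypoxia.

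**Figure D1:**
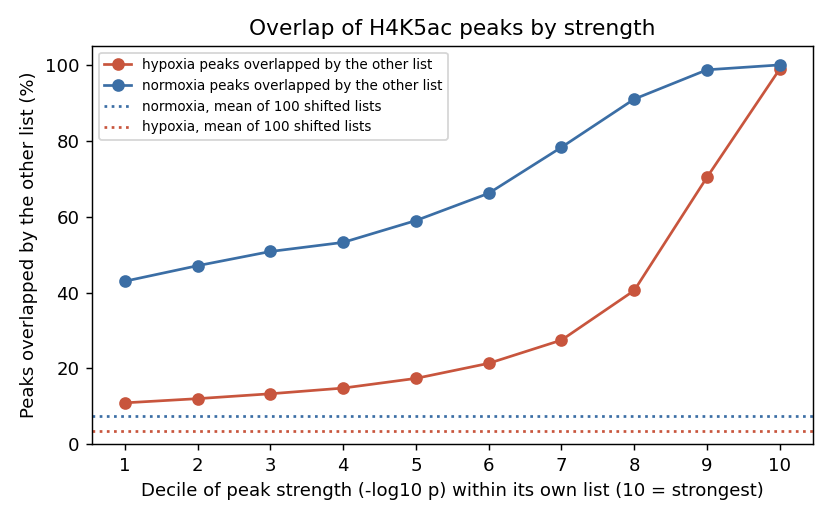
Share of peaks (%, y axis) overlapped by the other library's list, by decile of −log10 p within the peak's own list (x axis, 10 the strongest); each point is 1 decile of 1 library and dotted lines are the means of 100 shifted lists (7.49% for normoxia, 3.54% for hypoxia). The share climbs from 43.0% to 99.99% in normoxia and from 10.9% to 98.9% in hypoxia.

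Peaks found in both conditions lay at gene ends far more often than peaks of 1 list. In the hypoxia list, 21.5% of shared peaks (95% interval 21.2 to 21.8%) and 3.92% of hypoxia-only peaks (3.83 to 4.01%) overlapped the 1000 bp around a gene end. In the normoxia list the shares were 21.5% for shared and 4.23% for normoxia-only peaks. Shared hypoxia peaks were also wider than hypoxia-only ones (medians of 445 and 263 bp) and stronger (median −log10 q-values of 10.0 and 3.86). Among strong hypoxia peaks the gene-end shares were 36.0% for shared and 8.01% for hypoxia-only peaks. Gene-end shares were not matched on width or on strength within these classes. Strong hypoxia-only peaks were also more distant from genes: 21.2% (1384 of 6526; 20.2 to 22.2%) had a summit over 100 kb from any protein-coding gene, against 8.71% (8.44 to 8.98%) of strong shared hypoxia peaks. Of the 497 strong normoxia-only peaks, 12.3% (9.52 to 15.5%) lay that far away, against 6.82% (6.53 to 7.11%) of strong shared normoxia peaks. Over all peaks the shares were similar between the lists, at 17.9% of hypoxia-only and 18.3% of normoxia-only peaks. Both were above the shares of shared peaks, at 12.3% in the hypoxia list and 12.5% in the normoxia list.

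Most protein-coding genes carried H4K5ac at a gene end in both conditions, and genes marked in hypoxia alone outnumbered those marked in normoxia alone. Of 19974 genes, 13849 (69.3%) were marked in both, 2339 (11.7%) in hypoxia only, 215 (1.08%) in normoxia only and 3571 (17.9%) in neither. A peak at both ends of the gene was present for 4224 genes in hypoxia and 2104 in normoxia, whereas a peak at 1 end was present for 11964 and 11960. With the hypoxia list limited to its 120033 strongest peaks, 1136 genes were marked in hypoxia only and 482 in normoxia only. A strong hypoxia peak without any normoxia peak at the gene ends was found for 262 genes, and the converse for 20. Neighbouring genes can share 1 peak, so these are not independent units.

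CA9, which encodes a membrane carbonic anhydrase and is a classical target of the hypoxia-inducible factors, was the only one of the 16 preselected genes marked in 1 condition alone. Its hypoxia peak (chromosome 9, 35673476 to 35674156) had its summit 158 bp from the low-coordinate end of the gene (35673928 to 35681159). The peak had a fold of 4.36 and a −log10 q-value of 8.97 within the hypoxia list, so it was not strong, and with a −log10 q-value of at least 10 in both lists CA9 was no longer counted as marked in hypoxia. No normoxia peak lay within the CA9 span, which held 2 hypoxia peaks. The other 15 preselected genes were marked in both conditions. They included METTL4, the methyltransferase gene named in the culture protocol (chromosome 18, 2537530 to 2571505), with a fold of 8.87 in the normoxia list and 14.6 in the hypoxia list. HIF1A, which encodes the oxygen-regulated subunit of hypoxia-inducible factor 1, had 8.16 and 10.9. EPAS1, its paralogue, had 4.83 and 8.56 at its high-coordinate end. The angiogenic factor VEGFA had 3.85 and 3.93, and LOX, a collagen cross-linking enzyme, had 5.54 and 5.75. For the glucose transporter gene SLC2A1 and the vasodilator peptide gene ADM the highest peaks lay at opposite ends of the gene. SLC2A1 had 5.51 at its high-coordinate end in normoxia and 6.73 at its low-coordinate end in hypoxia, and ADM had 3.45 and 4.24 at the same respective ends. All folds given here are the authors' values, each relative to the background of its own library, and do not measure a change.

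**Figure D2:**
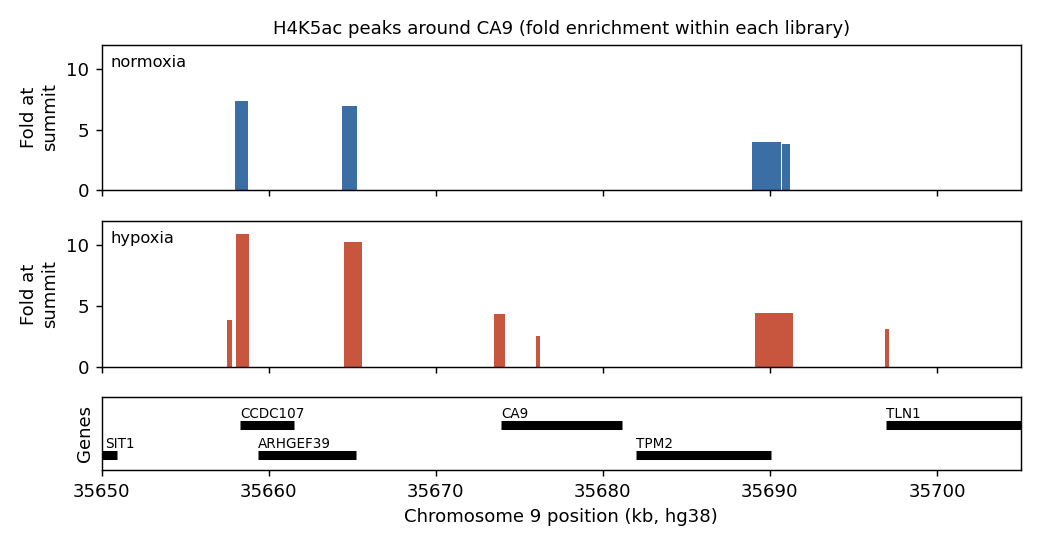
H4K5ac peaks around CA9 on chromosome 9 (x axis, kb, hg38) in normoxia (top) and hypoxia (middle), with gene spans below; each bar spans 1 peak and its height is the authors' fold at the summit within that library. The hypoxia peak with a fold of 4.36 at the low-coordinate end of CA9 has no normoxia counterpart, while the peaks at ARHGEF39 are present in both.

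The hypoxia-response genes were largely marked already in normoxia. Of 30 members, 26 were marked in both conditions, 2 in hypoxia only (CA9 and ANGPTL4, which encodes an inhibitor of lipoprotein lipase), none in normoxia only, and 2 in neither. ANGPTL4 (chromosome 19, 8364155 to 8374370) had a hypoxia peak with a fold of 3.58 and a −log10 q-value of 13.7. It was no longer counted with a 2000 bp window, which took in a normoxia peak. Of the 4 members without a normoxia peak at a gene end, 2 had a hypoxia gene-end peak, a share at percentile 65.2 of random lists (52.1% were as high). With equal list lengths the share lay at percentile 90.4 (16.8% were as high). Within the both class, ANKRD37 had folds of 12.6 in normoxia and 17.6 in hypoxia, and the mitochondrial protein gene FAM162A was marked with a fold of 14.4 in hypoxia. NDRG1, a stress-response gene on chromosome 8 (133237175 to 133297252), held 5 normoxia and 31 hypoxia peaks in its span, and 7 and 14 strong peaks within 50000 bp. The 1 Mb bin from 133 Mb that holds it had 19 strong normoxia and 65 strong hypoxia peaks. The background of this bin was 2.25 times the list's median in normoxia and 2.81 times in hypoxia. The list medians differed, at 5.07 reads in normoxia and 4.17 in hypoxia, so such multiples do not compare the libraries directly. Of the 20 glycolysis genes, 18 were marked in both conditions. HK1, a hexokinase gene (normoxia fold 3.42), and SLC2A3, a glucose transporter gene (3.31), were marked in normoxia only. Neither peak was strong, and their spans held more hypoxia than normoxia peaks (28 and 13 for HK1, 4 and 2 for SLC2A3). PFKM had 7.54 in normoxia and 11.4 in hypoxia, and HK2 had 7.23 and 8.43.

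Of the 25 mesenchymal and EMT transcription factor genes, 19 were marked in both conditions, 2 in hypoxia only and 4 in neither. The EMT transcription factor genes SNAI1 (fold 7.82 in normoxia, 8.46 in hypoxia), SNAI2 (3.33 and 4.99), TWIST1 (5.55 and 5.84) and ZEB1 (8.65 and 13.2) were marked in both, as were CDH2, the N-cadherin gene (4.59 and 6.91), and VIM, the vimentin gene (4.21 and 6.44). SPARC, a matrix protein gene (hypoxia fold 3.80), and MMP9, a matrix metalloproteinase gene (2.67), were marked in hypoxia only. Neither of these peaks was strong, and both genes held normoxia peaks elsewhere in their spans. The 2 of 6 unmarked members with a hypoxia peak lay at percentile 40.2 of random lists, of which 75.75% were as high. All 25 epithelial genes were marked in both conditions, including CDH1, the E-cadherin gene (3.89 and 7.08), and the junction genes MARVELD2 (8.42 and 13.5), CTNNB1 (8.98 and 11.9), TJP1 and CLDN1. Marking in both does not require the same gene end. Among the epithelial genes OVOL2 alone, named after its values were seen, had its highest peaks at opposite ends. The normoxia peak lay at the high-coordinate end (fold 4.48, −log10 q-value 18.9). The hypoxia peak lay at the low-coordinate end (fold 2.80, −log10 q-value 2.70) and was not strong.

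Squamous genes without a normoxia peak at a gene end all had a gene-end peak in hypoxia. Of 20 members, 15 were marked in both conditions and 5 in hypoxia only. The 5 were TP63, the master regulator of stratified epithelium (hypoxia fold 5.66), IVL, the cornified envelope protein involucrin (3.98), the keratin gene KRT6B (3.32), the small proline-rich protein gene SPRR3 (3.07) and the cadherin gene FAT2 (2.87), which was named after its value was seen. Of these peaks, that of TP63 alone was strong, with a −log10 q-value of 10.6, and the FAT2 span held 9 normoxia peaks. All 5 unmarked members thus had a hypoxia peak, and 0.95% of random lists had as many (percentile 99.5). This was the highest percentile among the lists, with no allowance made for picking the highest. IVL and SPRR3 lie near each other on chromosome 1. The random lists were not matched on such clustering or on normoxia peaks elsewhere in the gene span. With equal list lengths 2 squamous genes were marked in hypoxia only, at percentile 85.2 (24.8% of random lists were as high), below the 90.4 of hypoxia-response genes. The TP63 peak lay at the low-coordinate end of a span that held 22 normoxia and 35 hypoxia peaks. KRT6B has near-identical keratin copies, so its reads are uncertain.

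Housekeeping, cell cycle and histone acetylation genes were marked in both conditions with 1 exception, HDAC8. All 20 ribosomal protein and housekeeping genes and all 20 cell cycle and E2F genes were marked in both conditions, for example RPL11 (fold 10.4 in normoxia, 15.1 in hypoxia), RPS3 (8.10 and 14.8), CDK1 (9.31 and 15.1) and MCM2 (9.62 and 13.8). HPRT1 was also marked in both. RPS6 had 8.12 and 13.6, CCNB1 had 6.69 and 12.9, and MKI67 had 7.00 and 11.6. Of 25 histone acetylation genes, 24 were marked in both, among them the acetyltransferase genes KAT7 (11.8 and 17.9) and KAT2A (8.40 and 10.3) and the deacetylase gene HDAC4 (9.27 and 11.3). HDAC8 was marked in hypoxia only, by a peak that was not strong (fold 3.30, −log10 q-value 3.26). Its span held 2 normoxia and 2 hypoxia peaks. With this single member unmarked in normoxia, the list lay at percentile 80.1, and 39.8% of random lists were as high. Of 25 genes of other lineages, 5 were marked in both, 9 in hypoxia only and 11 in neither. The hypoxia-only members included the T cell gene CD3E (fold 5.05), the globin gene HBB (3.54), the endothelial gene PECAM1 (3.19) and the cardiac troponin gene TNNT2 (3.13). These 9 of 20 unmarked genes lay at percentile 68.0 of random lists, of which 40.1% were as high. Of all genes unmarked in normoxia, 39.6% had a hypoxia peak.

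**Figure D3:**
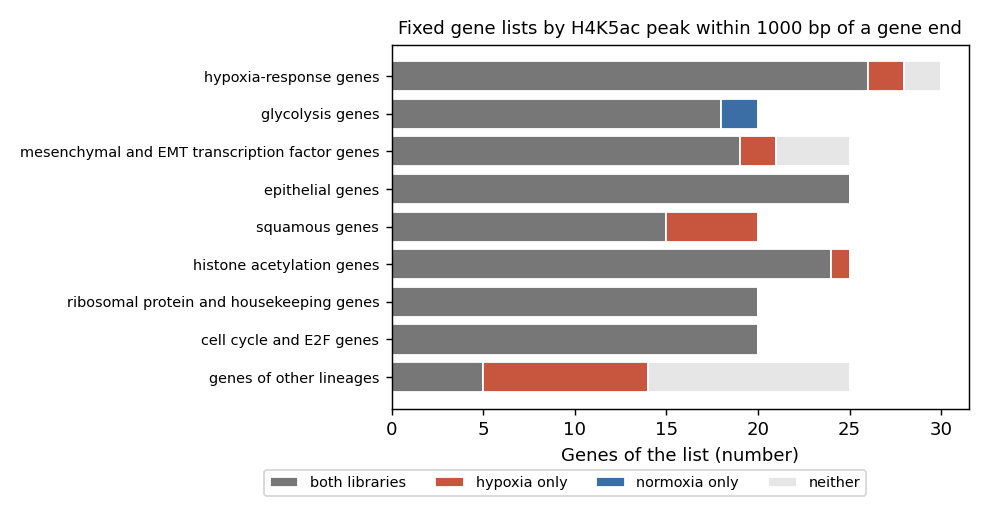
Number of genes (x axis) of each of the 9 fixed lists (y axis) with an H4K5ac peak within 1000 bp of a gene end in both libraries, in hypoxia only, in normoxia only or in neither. Hypoxia-only genes number 5 of 20 squamous genes and 9 of 25 genes of other lineages, against 2 of 30 hypoxia-response genes.

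The highest-ranked genes marked in hypoxia alone belonged to several unrelated groups and included members of multi-copy families. They were the zinc finger gene ZNF595 (hypoxia fold 9.20), GAGE13 (8.73), MSN, which encodes the actin-membrane linker moesin (8.02), the germ cell gene ASZ1 (7.55), POTEH (7.55), the acyl-CoA synthetase gene ACSS3 (7.31), F8A1 and H2AB1, which share 1 peak (7.31), the platelet chemokine gene PF4 (7.31) and TRIM74 (7.31). GAGE13, POTEH, F8A1, H2AB1 and TRIM74 have near-identical copies, and their reads are uncertain. The MSN peak (chromosome X, 65588113 to 65588764) had a −log10 q-value of 19.9. The MSN span held 7 normoxia and 9 hypoxia peaks, and the ACSS3 span 1 and 5. The highest-ranked genes marked in normoxia alone were the melanocortin receptor gene MC5R (normoxia fold 5.33), CARD16, a caspase recruitment domain gene (5.13), SYNPO2 (5.09), PRR32 (4.85), TRMT9B (4.85), the phosphatase gene DUSP19 (4.79), the DNA sensor gene AIM2 (4.71), the matrix Gla protein gene MGP (4.69), LOC107986837 (4.54) and CFAP126 (4.32). Hypoxia peaks lay elsewhere in the spans of AIM2 (10), SYNPO2 (6), TRMT9B (5), LOC107986837 (5) and MGP (1). With no peak of the other library within 2000 bp, strong peaks marked 169 genes in hypoxia alone and 1 gene, CARD16, in normoxia alone. Here too the normoxia peaks were screened against the longer list. The highest folds among gene-end peaks belonged to genes marked in both conditions. In normoxia these were POLR2J3 (20.4), LOC102724594 and LOC102724652 (1 shared peak, 20.1), the splicing factor gene U2AF1 (19.9) and LRRIQ1 (17.8). In hypoxia they were ISLR2 (25.4), U2AF1 (24.1), ING3, a histone acetyltransferase complex subunit (23.9), and LOC102724594 and LOC102724652 (23.8). POLR2J3, U2AF1 and the LOC genes also have near-identical copies.

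The excess of hypoxia peaks was uneven along the genome, and the 3 bins of 1 Mb with the largest difference in strong peak numbers lay on chromosome 11. Genome-wide, strong peaks numbered 48782 in hypoxia and 29967 in normoxia, a ratio of 1.63. By chromosome the ratio ranged from 1.43 on chromosome 4 to 2.15 on chromosome 14, with 2.10 on chromosome 8. Between 69 and 72 Mb of chromosome 11, 505 strong hypoxia peaks faced 123 strong normoxia peaks, a ratio of 4.11 (95% counting interval 3.37 to 5.04). Other bins held fewer peaks in more unequal numbers, such as 55 in hypoxia and 3 in normoxia from 3 Mb of chromosome 5, and 57 and 6 from 17 Mb of chromosome 9. The genes between 69 and 72 Mb of chromosome 11, named after their values were seen, include the scaffold gene SHANK2 (179 strong hypoxia and 22 strong normoxia peaks within 50000 bp), PPFIA1 (69 and 10), the actin regulator CTTN (39 and 4), the chloride channel gene ANO1 (72 and 27) and the cyclin D1 gene CCND1 (29 and 7). Strong peaks in these 3 Mb had low folds, with medians of 2.26 in hypoxia and 2.81 in normoxia, against 5.90 and 5.50 elsewhere.

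**Figure D4:**
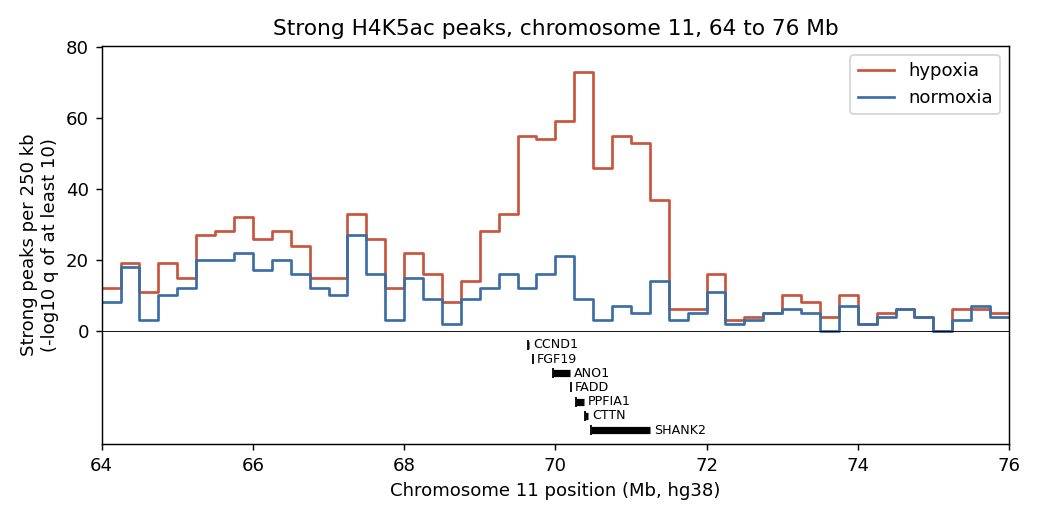
Strong H4K5ac peaks per 250 kb (y axis) along chromosome 11 from 64 to 76 Mb (x axis, hg38) in hypoxia and normoxia, with the spans of 7 genes below. Between 69 and 72 Mb the hypoxia library has 505 strong peaks and the normoxia library 123.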

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

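Stitching, windows and list limits were planned; leaving out chromosome 11 from 69 to 72 Mb, a one-sided q-value threshold and whole gene spans were added after the data were seen. Of 62 values recomputed, 21 stayed within their interval or within 1.5 times the main count and 41 moved; the gene-end share difference, the only one with a sign, kept it. The normoxia share overlapped (68.7%) was 82.6% and 89.2% with a −log10 q-value of at least 5 and 10 in both lists, 54.4% with equal list lengths, 52.3% with 50% reciprocal overlap, 70.1% with stitching, and 98.3% for strong normoxia peaks against all hypoxia peaks. The hypoxia share (32.7%) was 38.0%, 56.7%, 54.1%, 24.3%, 32.9% and 86.6% in the same order. The gene-end share of hypoxia-only minus shared regions (-17.6 percentage points) was -29.3, -34.2, -21.5, -18.8, -16.3 and -28.0 in that order, and -16.3 and -18.1 with windows of 500 and 2000 bp. Genes marked in hypoxia only (2339) numbered 1381 at a −log10 q-value of 10, 1136 with equal list lengths and 262 for strong peaks against all normoxia peaks. Genes marked in normoxia only (215) numbered 128 and 119 at −log10 q-values of 5 and 10, 482 with equal list lengths, 20 for strong peaks against all hypoxia peaks and 100 over whole gene spans. Hypoxia-response genes marked in hypoxia only (2) numbered 1 at a −log10 q-value of 10 in both lists, at that threshold in hypoxia alone, with the 2000 bp window and over whole spans. At a −log10 q-value of 5 in both lists they numbered 3. The mesenchymal and EMT genes (2) numbered 1 at a −log10 q-value of 5, with equal list lengths and with the 2000 bp window, and 0 at a −log10 q-value of 10 in both lists or in hypoxia alone and over whole spans. With the 500 bp window they numbered 3. With equal list lengths, squamous genes went from 5 to 2, histone acetylation genes from 1 to 0 and genes of other lineages from 9 to 4. Counts as small as these rest on single peaks. Stricter thresholds and equal list lengths leave fewer peaks to count by construction; for the other settings the cause was not tested. The planned hypoxia response element comparison was not run, since it needs genome sequence. No paired analysis was possible because each condition had 1 library. A weak peak missing from 1 list is not shown to be absent at that site, and how far depth limits such peaks was not tested.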

Other observations

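The thinning tests of the whole list and the comparison of peaks within 50000 bp of list genes were chosen after their results were seen, and the other tests before, on patterns found in the same data. Outside the 3 Mb of chromosome 11, long stretches of chromosomes 14, 9 and 15 also held many more strong peaks in hypoxia. Of the 20 bins of 1 Mb with the largest excess, 10 lay on chromosome 14, and from 89 to 97 Mb of that chromosome the background was 2.32 to 3.04 times the list's median in normoxia and 2.86 to 3.85 times in hypoxia. In the 2 such bins on chromosome 15 it was 2.39 and 3.14 times in normoxia and 3.30 and 4.99 times in hypoxia. Each multiple is of its own list's median, which was lower in hypoxia (4.17 reads) than in normoxia (5.07), and this raises the hypoxia multiples. Background was close to the median in other bins with such an excess: 1.24 and 1.27 times in normoxia and hypoxia from 5 Mb of chromosome 9, 0.986 and 1.23 times from 17 Mb of it, and 1.16 and 1.27 times from 81 Mb of chromosome 14. The 10 genes outside 69 to 72 Mb of chromosome 11 with the largest excess in their spans were chosen after their values were seen. The phosphatase gene PTPRD on chromosome 9 had 48 strong hypoxia and 8 strong normoxia peaks, ADAMTSL1 had 42 and 10, CCDC171 had 33 and 5, CNTLN had 29 and 5, and the histone demethylase gene KDM4C had 25 and 3. On chromosome 14, the forkhead factor gene FOXN3 had 38 and 10, CEP128 had 33 and 7, UNC79 had 26 and 3, and SIPA1L1 had 30 and 8. On chromosome 15, the protease gene ADAMTS17 had 31 and 9.

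Peaks within 50000 bp of list genes gave a different order of lists from peaks at gene ends. Over all peaks the hypoxia to normoxia ratio was 2.16 for histone acetylation genes, at percentile 98.9 of lists matched on normoxia peak number, and 1.51 for mesenchymal and EMT genes, at percentile 0.05, beside 1.98 for all genes. It was 1.61 for squamous genes (percentile 4.08), 1.75 for hypoxia-response genes (16.1), 1.88 for glycolysis genes (41.6), 1.80 for epithelial genes (42.0), 1.75 for ribosomal protein and housekeeping genes (18.8), 1.62 for cell cycle and E2F genes (5.83) and 2.20 for genes of other lineages (70.4). Over strong peaks alone, where all genes had 1.45, squamous genes had 1.67 (percentile 96.2), from sums over genes of 135 and 81. Some members lie close together and share peaks. With each peak counted once, the squamous list had 113 strong hypoxia and 68 strong normoxia peaks, a ratio of 1.66. The random lists were not matched on such clustering or on gene length, so the percentiles of clustered lists and of lists with long genes are uncertain. Over all peaks, all 25 histone acetylation genes had more in hypoxia, and HDAC4 alone had 89 against 23 in normoxia. No allowance was made for picking the highest or lowest percentile. Strong-peak ratios were 1.39 for mesenchymal and EMT genes (percentile 34.1), 1.49 for histone acetylation genes (89.1) and 1.36 for hypoxia-response genes (37.7). The remaining lists had strong-peak percentiles of 44.0 (glycolysis), 86.2 (epithelial), 40.5 (ribosomal protein and housekeeping), 78.1 (cell cycle and E2F) and 36.8 (other lineages).

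The hypoxia list held 2.15 times as many peaks as the normoxia list, which a difference in depth could produce. Hypoxia pileups were thinned to 84.6% to equal the implied normoxia depth. The ratio of peaks with a −log10 p of at least 10 went from 1.78 to 1.47 (95% counting interval 1.45 to 1.49), and with equal fragment lengths, an alternative added later, to 1.70 (1.67 to 1.72). Under either assumption depth does not account for all of the excess among these peaks, and the part it accounts for depends on the fragment lengths, which are inferred. For weaker peaks, which make up most of both lists, the effect of depth was not tested. Thinning lowered pileups but left peak boundaries as called, and the ratio of peak numbers was not recomputed on stitched peaks. How far narrower peaks in hypoxia raised the number of peaks was therefore not tested. Better immunoprecipitation or library quality in hypoxia and a response of the cells to hypoxia cannot be told apart with 1 library per condition.

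Strong hypoxia peaks crowded between 69 and 72 Mb of chromosome 11, a region that FaDu cells may carry in extra copies. The recovered background in its 3 bins was 8.84 to 12.3 times the list's median in normoxia and 13.7 to 19.95 times in hypoxia, so high coverage was present in both libraries. In reads, which do not depend on the differing list medians, it was 44.8 to 62.3 in normoxia and 57.2 to 83.2 in hypoxia. Depth alone is argued against by peaks with a −log10 p of at least 10. Their ratio in the region was 3.88 before thinning and 3.34 (2.80 to 4.01) after it, beside 1.47 elsewhere after thinning. Among strong peaks with a fold of at least 4, the ratio in the region was 1.67 (35 and 21 peaks; 0.944 to 3.01), equal to the 1.66 elsewhere, so the excess lay in peaks of low fold. That fold limit lay above the median fold of strong peaks in the region (2.26 in hypoxia, 2.81 in normoxia), and so few peaks leave a wide interval. The test therefore does not decide whether amplified DNA let weak enrichment pass the threshold. Cultures that differ in copy number and hypoxia itself also remain open, untested.

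Strong hypoxia-only regions lay over 100 kb from genes in 21.2% of cases, against 8.71% of strong shared ones. Strong normoxia-only regions also exceeded their shared ones (12.3% and 6.82%). Over all peaks 1-list regions were alike (17.9% in hypoxia, 18.3% in normoxia), and both exceeded their shared ones (12.3% and 12.5%). Shared regions weighted to the same −log10 q-value had 13.1% (12.5 to 13.7%), which argues against peak strength alone. Among regions whose background was at most 2 times the genome-wide value, the shares were 28.3% (26.99 to 29.7%) for hypoxia-only and 20.7% (19.99 to 21.4%) for shared regions, which argues against coverage alone. With both limits together the shared regions had 21.1% (20.1 to 22.1%), so strength and coverage narrow the gap without closing it. Repeated sequence and ambiguous mapping, which may be common far from genes, were not tested, and since peaks of 1 list in either condition share the trait, it is not shown to be particular to hypoxia.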
